A study of Homo sapiens with 52 samples.

How the data were processed

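Contacts of the genome with the nuclear lamina were measured by single-cell DamID in KBM7 cells. KBM7 is an established human chronic myeloid leukaemia line. In DamID, the bacterial methyltransferase Dam is fused to a protein of interest, here Lamin B1 of the nuclear lamina, and methylates adenines in DNA that comes close to it. Per the labels' protocols, methylation was induced with 0.5 nM Shield1 for 15 h. The smallest 2% of cells positive for both Fucci markers, which report cell cycle phase, were sorted singly. Their DNA was digested with DpnI, which cuts methylated sites, ligated to adapters and amplified with 21 PCR extension steps. Cutadapt and Bowtie2 2.1.0 were used with the human genome build hg19, per the submitters' processing notes.

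The authors' deposited values are ratios of observed to expected signal (OE) in 30376 bins of 100 kb, 1 column per cell. What the expected value was made from, how duplicate reads were treated and why some bins hold no value are not given in the sources used here. The labels describe 52 cells of clone 14, with ploidy 2N, which form 1 group. The 51 cells with a column were used, and cell 47 was not analysed here. The bins run along chromosomes 1 to 8, 10 to 21 and X, and along 2 joined sequences of chromosomes 9 and 22, named 9:22 and 22:9 in the file. Positions on the joined sequences count along the joined sequence. A total of 3792 bins had no value in any cell and were left out, among them all 1464 bins of chromosome 8 and the stretch of chromosome 15 from 61000001 to 89900000. The other 26584 bins had a value in every cell, and 1985 of these were 0 in every cell.

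The deposited ratios hold a count for each bin and cell, called reads here. Each value above 0 was a whole number of reads, times a factor of the cell, divided by a whole number of the bin (called the expected number here). All values above 0 (100%) came out whole within 0.02 reads. The expected number had a median of 316 per bin, and 24037 bins had at least 100. No bin held more reads than its expected number in any cell, and the highest ratio of reads to that number was 1. Such a ceiling would arise if each site counted at most 1 time. The recovered reads may therefore be distinct sites rather than all sequenced reads, and depth here means their total. The recovered reads ranged from 50978 in cell 9 to 316463 in cell 26, with a median of 142540. At an OE of 1, a bin of median expected number held 2.12 reads in cell 9 and 13.2 in cell 26, so calls in single bins of shallow cells rest on few reads. The recovery was tested on simulated data over 23588 bins. A first version gave a simulated cell a total too high by a whole factor. The check of cell factors was then extended, which left the reads of the real cells as they were, and 99.998% of simulated values above 0 were recovered.

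A bin was called in contact in a cell at an OE of at least 1, and the contact frequency of a bin was the share of the 51 cells in contact. Intervals of single-cell shares are Wilson intervals at the 95% level. They cover counting error over bins only, since neighbouring bins are not independent and PCR reads carry no molecular identifiers. The spread of contact frequency and the mean phi correlation of pairs of cells were set against 1000 draws in which each cell's profile was rotated by a random offset along the joined chromosomes. Run lengths and coordination were set against 100 draws in which cells were permuted within each bin. For coordination, bins with a contact frequency from 20% to 80% were used, the share of each cell was subtracted, and correlations between bins of different chromosomes were the baseline. On simulated contacts over 26584 bins that varied independently, the run length ratio was 0.999. With a planted correlation of 0.0638 along chromosomes, coordination gave 0.0614 at 1 Mb and 0.0609 at 50 Mb.

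With 1 group there was no comparison between groups. Comparisons were made between chromosomes and regions within the same cells. Sign-flip tests over cells had been planned for chromosome 18 against chromosome 19 and for chromosome ends. The labels name no separate cultures, so the cells of the clone were counted as 1 sample and no p-value over cells is given. Differences are given with their SD over cells and the number of cells with each direction, which describe these cells only. The named chromosomes were the 3 with the highest and the 3 with the lowest contact share, plus 18, 19 and X. The named regions were the 5 longest runs of bins contacted in at least 90% of cells and the 5 longest in at most 5% of cells. These rules, the OE threshold and the first set of alternatives were set before the data were examined. That set held OE thresholds of 0.5 and 2, the top 30% of bins in each cell, bins with a read in any cell, odd-numbered or even-numbered cells, 500 kb bins, numbered chromosomes only, other end widths, and log2(OE + 0.1) for coordination. Others were added after the data were seen. The planned relations to gene density, GC content and gene lists were not run, and no genes are named, since a gene annotation of hg19 was not used here. A gene table of another assembly was not used. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.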

Results

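Lamina contacts were mapped in single KBM7 cells, a human chronic myeloid leukaemia line, by DamID with a fusion of Dam to Lamin B1, a structural protein of the nuclear lamina. The 51 cells analysed came from clone 14, formed 1 group with a ploidy of 2N and yielded 50978 to 316463 recovered reads each. The values were ratios of observed to expected signal (OE) in 26584 bins of 100 kb on hg19, and a bin was taken as contacted at an OE of at least 1. No separate cultures are named, so the cells count as 1 sample, and SDs describe the spread between these cells.

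How much of the genome touched the lamina in a single cell was examined first. Contacted bins made up 31.5% ± 3.56 (SD, n = 51 cells) of the measured genome. The lowest share was 24.1% in cell 42 (95% Wilson interval 23.6% to 24.7%) and the highest was 39.9% in cell 26 (39.3% to 40.5%). These intervals treat bins as independent, which neighbouring bins are not, so they are too narrow. The low share of cell 42 was uneven over chromosomes. It had contact in 10.2% of bins on chromosome 5 (mean of cells 36.9%) and 7.57% on chromosome 10 (29.1%). On chromosomes 3 and 4 it had 42.8% (37.2%) and 46.8% (43.6%). Of all values, 50.1% were 0, while 11.5% lay from 1 to under 2 and 20.0% at 2 or above. The median OE of contacted bins was 2.40. Reads in bins contacted in at most 5% of cells, a measure of background, made up 2.01% ± 1.04 (SD, n = 51) of a cell's reads, from 0.624% in cell 29 to 4.98% in cell 26. These bins were chosen from the same calls, so a cell's own rare contacts count towards this measure.

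Whether the same regions touched the lamina in different cells was examined next. Most bins were contacted in either very few or most cells. No cell had contact in 10299 bins (38.7%). Of these, 1985 held no read in any cell. Their expected number is unknown, and no limit is given for them. For the other 8314, 0 of 51 cells allows a share of cells with a contact call of up to 5.88% by the limit of 3 counts. At the other end, 5549 bins (20.9%) were contacted in at least 80% of cells, and 219 bins (0.824%) in all 51, for which the lower exact two-sided 95% limit, a different rule, is 93.0%. Both limits treat the cells as independent draws. They also take no account of the bins having been picked by their counts, so they may be too narrow. At an OE of at least 2, the share of bins contacted in at least 80% of cells was 4.24%. The share contacted in no cell was 48.8% at that threshold and 29.2% at an OE of at least 0.5. A further 5868 bins (22.1%) lay above 20% and under 80%. The SD of contact frequency over bins was 0.372, against at most 0.0693 in 1000 draws with rotated profiles. Pairs of cells had a mean phi correlation of 0.635 (SD 0.0538 over 1275 pairs, range 0.480 to 0.762), against at most 0.00288 in the rotated draws. Contact frequencies in the 25 odd-numbered and the 26 even-numbered cells correlated over bins with a Pearson's r of 0.979 and a Spearman's rho of 0.957. These correlations are across bins, which are not independent.

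**Figure D1:**
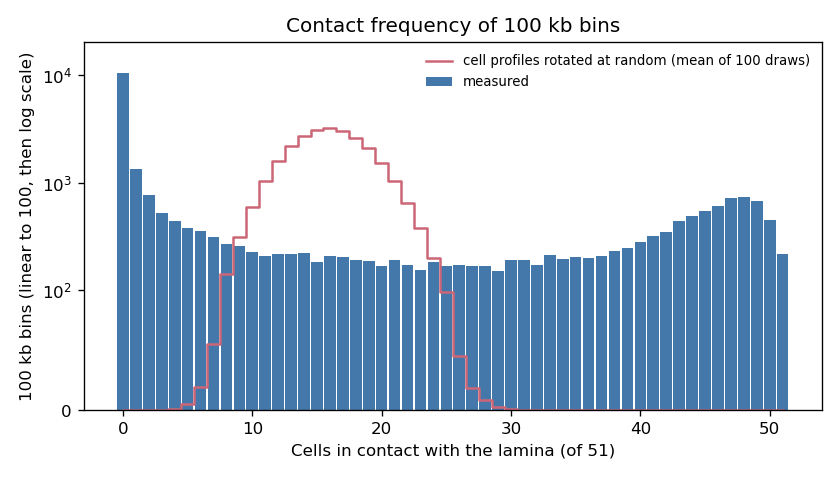
Number of 100 kb bins (y axis, linear to 100 and logarithmic above) by the number of cells in contact (x axis), as measured (bars) and as the mean of 100 draws with cell profiles rotated at random (line). The measured bins pile up at 0 cells (10299 bins) and at high numbers of cells, with 731 bins at 48 cells and 219 at 51. Rotated profiles leave no bins at these numbers of cells.

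The 5 longest runs of bins contacted in at least 90% of cells, among 923 such runs, lay on chromosomes 3 and 4. The longest run of bins contacted in at least 90% of cells covered 3.4 Mb of chromosome 3 from 172800001 to 176200000 (hg19). Its bins were contacted in 98.1% ± 3.05 (SD, n = 51), its mean OE was 3.43, and 30 of the 51 cells were in contact over its whole length. On chromosome 4, the region from 136000001 to 139000000 was contacted in 97.1% ± 4.52 of its bins, with a mean OE of 3.21. Also on chromosome 4, the region from 96100001 to 98900000 was contacted in 96.4% ± 7.58 and the region from 92100001 to 94600000 in 94.7% ± 9.82. The region of chromosome 3 from 20400001 to 22900000 was contacted in 96.0% ± 6.60. None of the 51 cells lacked contact over the whole of any of these 5 regions. At an OE of at least 2 the contacted shares of these regions were 75.7% to 86.4%.

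Long regions were almost without contact. The longest run of bins contacted in at most 5% of cells covered 30.1 Mb of chromosome 1, from 17200001 to 47300000, with contact in 0.0456% ± 0.176 (SD, n = 51) of its bins, and 47 cells had no contact in it. Both sides of chromosome 19 were of this kind. Contact covered 0.0196% ± 0.0980 of the bins from 200001 to 20200000 and 0.0520% ± 0.132 of those from 32700001 to 59100000. On chromosome 11 the region from 59200001 to 78500000 was contacted in 0.0610% ± 0.198 of its bins. On the joined chromosome 9:22 the region from 125500001 to 138900000 of the joined sequence was contacted in 0.117% ± 0.481. These low shares rest on few contacts and moved with depth. After all cells were thinned to 50978 reads the first chromosome 19 region stood at 0.196%, the second at 0.163%, and the regions of chromosomes 1, 11 and 9:22 at 0.117%, 0.213% and 0.176%. In each region 45 to 94 bins held no read in any cell, and their expected number is unknown. The bins with reads had median expected numbers of 275.5 to 322, against 316 over the genome.

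Chromosomes differed widely in contact. Chromosome 18 had the highest share of contacted bins, 46.9% ± 6.80 (SD, n = 51), above the genome's share in 50 of 51 cells. Chromosome X (43.7% ± 5.99) and chromosome 4 (43.6% ± 4.94) lay above the genome's share in all 51 cells. The lowest were the joined chromosome 22:9 (0.662% ± 0.870, over 148 bins with a value), chromosome 19 (2.20% ± 2.1) and chromosome 17 (9.54% ± 3.56), each below the genome's share in all 51 cells. At an OE of at least 2 chromosome 17 stood at 5.14% and chromosome 19 at 0.760%, and at an OE of at least 0.5 chromosome 19 stood at 3.86%. Without the bins that held no read in any cell, chromosome 17 stood at 12.2%, chromosome 19 at 2.80% and the genome at 34.0%. The value of 22:9 rests on bins of low expected number, since it was 0.0472% without the 10 bins under 100 and the 55 bins without a read. Of the 22 chromosomes and joined chromosomes, 5 lay above the share of the cell's own genome in at least 90% of cells and 6 lay below it in as many.

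**Figure D2:**
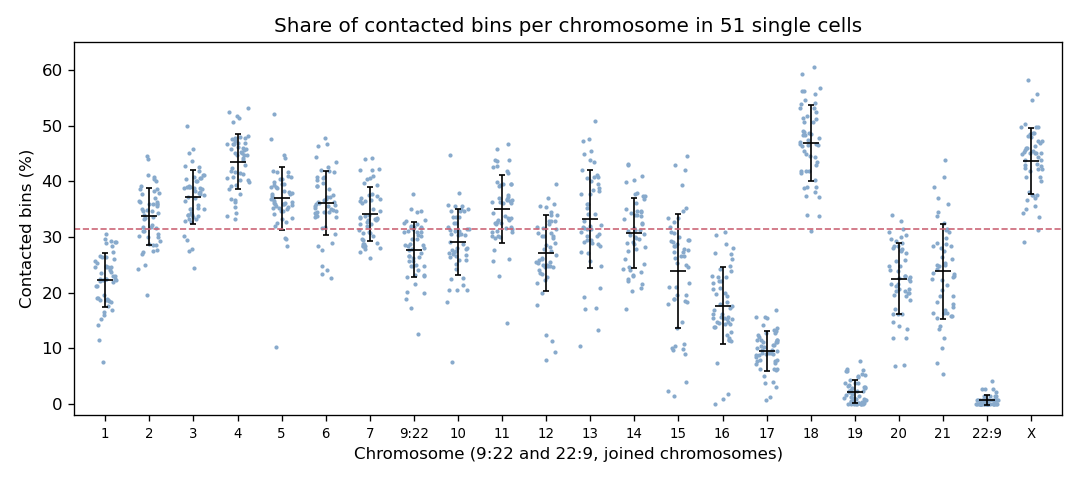
Share of contacted bins (y axis, %) on each chromosome or joined chromosome (x axis) in 51 single cells (points), with the mean and SD over cells (black) and the mean genome share of 31.5% (dashed line). Chromosomes 18, X and 4 lie highest, and 22:9, 19 and 17 lowest.

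Textbooks describe chromosome 18 as gene-poor and chromosome 19 as gene-rich. Their contact shares differed by 44.7 percentage points ± 6.51 (SD, n = 51), and chromosome 18 was higher in all 51 cells. Contact on chromosome 18 was spread over many bins, with 36.1% of its 751 bins contacted in at least 80% of cells. No bin of the 560 on chromosome 19 reached that frequency, 86.8% were contacted in no cell, and 8 cells had no contact on this chromosome at all. The 27 bins of chromosome 19 contacted in at least 20% of cells all lay between 20300001 and 32500000, an interval noted after the values were seen. It holds the chromosome's longest inner stretch without values, from 24700001 to 27700000. Bins within 5 Mb of that stretch were contacted in 12.2%, against 0.0384% of the chromosome's other bins.

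Chromosome ends were contacted less often than the rest. Bins within 5 Mb of the outermost measured bins were contacted in 13.4% ± 2.57 (SD, n = 51), against 33.1% ± 3.69 for other bins. The difference of -19.7 points ± 2.19 had the same direction in all 51 cells. It was present in the pooled cells on 19 of the 22 chromosomes and joined chromosomes. It was largest on chromosome 6, where 3.18% of end bins and 38.1% of other bins were contacted. Chromosomes 3, 15 and 22:9 went the other way, by 1.09, 5.52 and 1.00 points. On chromosomes 13, 14, 15 and 22:9 no inner stretch without values marked the centromere. Many of their bins had no value, with 962 of 1152, 881 of 1074, 520 of 1026 and 148 of 312 measured. An outermost measured bin may there lie beside the centromere, so values of these chromosomes may not describe ends alone. Contact rose from 6.61% ± 2.26 within the outermost 1 Mb to 28.9% ± 4.15 from 5 to 10 Mb.

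**Figure D3:**
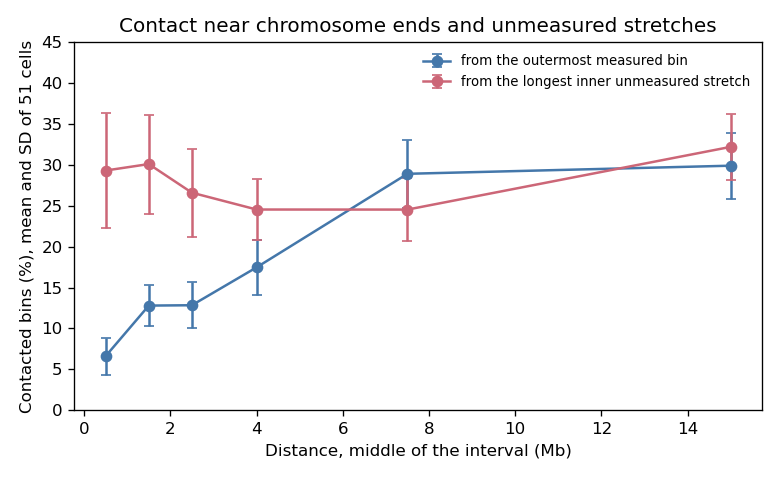
Share of contacted bins (y axis, %; mean and SD of 51 cells) by distance (x axis, Mb, middle of the interval) from the outermost measured bins of chromosomes and from the longest inner stretch without values. Contact is 6.61% in the outermost 1 Mb and 29.3% in the 1 Mb beside the unmeasured stretches.

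Whether neighbouring bins touched the lamina together in the same cell was examined through the length of uninterrupted contact. Runs of contacted bins had a mean length of 0.530 Mb, 1.49 times the 0.356 Mb of draws that kept each bin's contact frequency but permuted the cells. None of 100 draws exceeded 0.357 Mb. All 51 cells had a mean run length above the mean of the draws. Of the 80547 runs, 36.1% were 1 bin long and 16.2% reached at least 1 Mb, and these longer runs held 57.0% of all contacted bins. The longest run covered 13.8 Mb of chromosome 5, from 17600001 to 31400000, in cell 46.

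Signal and run length were also compared between classes of bins by contact frequency. Classes, signal and runs come from the same OE values and are not independent measures. The median OE of contacted bins was 1.44 ± 0.119 (SD, n = 51) where at most 20% of cells had contact and 2.85 ± 0.265 where over 80% had. The run holding a contacted bin had a mean length of 0.560 Mb ± 0.150 in the first class and 1.87 Mb ± 0.376 in the second. The difference of 1.31 Mb ± 0.309 had this direction in all 51 cells. Draws that permuted cells within bins gave a difference of 1.08 Mb (highest of 100 draws 1.09 Mb), so most of it was present without any link between bins of the same cell. The measured difference depended on depth and on the OE threshold, with 0.980 Mb after all cells were thinned to 50978 reads and 0.573 Mb at an OE of at least 2.

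Contacts of separate bins varied together from cell to cell along a chromosome. Over 5868 bins of intermediate contact frequency, the mean correlation above that between chromosomes was 0.437 for adjacent bins, 0.266 at 1 Mb, 0.0783 at 10 Mb and 0.0418 at 50 Mb. The highest of 100 draws with cells permuted within bins was 0.00498, 0.00869, 0.0102 and 0.0143 at these distances. The correlation lay above the baseline on all 20 chromosomes with enough pairs of bins at 1 Mb and on all 14 at 50 Mb. Bins of different chromosomes had a mean correlation of -0.00384. Subtracting each cell's share pushes this value below 0. Draws that permuted cells separately for each chromosome gave -0.00597 to -0.00567, so the measured value lay slightly above them.

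**Figure D4:**
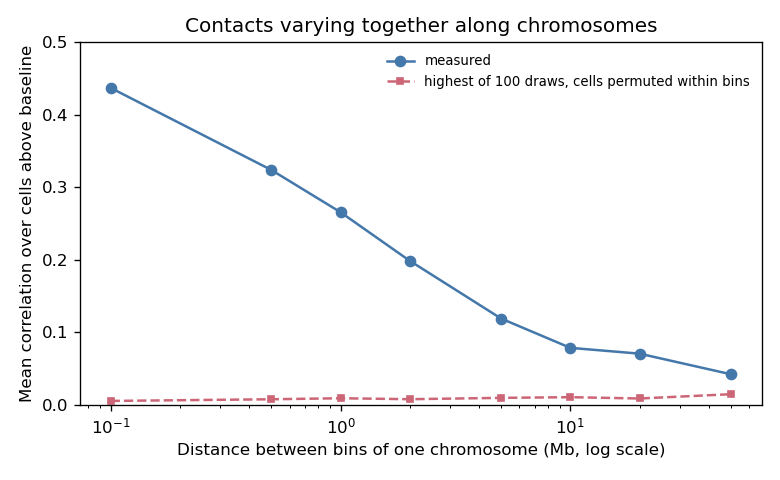
Mean correlation over 51 cells of contact between bins of one chromosome, above that between chromosomes (y axis), by distance (x axis, Mb, log scale), with the highest of 100 draws in which cells were permuted within bins (dashed). The measured values fall from 0.437 at 0.1 Mb to 0.0418 at 50 Mb and stay above the draws.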

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

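Chosen after the data were seen were the minimum expected number, the thinning to one depth, the omission of 5 cells of high background, the run length draws that also keep each cell's share, the permuted reference for frequency classes, and the comparison of flanks in every setting. The other alternatives were chosen before. Under the alternatives run, 287 of 313 values kept their direction and their side of the threshold, or moved by less than the spread between cells. None reversed. With an OE of at least 0.5, the contact share was 38.8% and the run length difference between the highest and lowest frequency classes was 1.79 Mb. With an OE of at least 2, the contact share was 20.0%, bins contacted in at least 80% of cells made up 4.24%, 3 chromosomes lay above the genome in at least 90% of cells, and the run length difference was 0.573 Mb. After thinning all cells to 50978 reads that difference was 0.980 Mb. The shifts in the contact share and in bins contacted in at least 80% of cells follow from the threshold itself. For the number of chromosomes above the genome and for the run length difference, the cause was not tested. Chromosome 18 exceeded chromosome 19 by 31.2 to 51.5 points, and ends differed by -22.8 to -12.3 points. Among named regions, the rarely contacted ones reached 0.267% to 0.417% at an OE of at least 0.5. The run length ratio ranged from 1.24 to 1.5, and coordination above the baseline from 0.191 to 0.377 at 1 Mb and from 0.0301 to 0.0631 at 50 Mb. The settings listed beforehand for gene density, GC content and gene lists were not run, since an hg19 annotation was not used here. Depth limits single-bin calls most in cell 9, where a median bin at an OE of 1 held 2.12 reads.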

Other observations

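The comparison beside unmeasured stretches and the subtraction of background were chosen after the data were seen, and the tests of read depth, copy number, chromosome arms and acrocentric chromosomes were set out before their results. For these ratio tests, the rule that the whole interval must pass the bound was adopted after a first run, and it turned the outcome of both depth tests from excluded to undecided. The depth test of contacts varying together was later judged by a comparison with draws from the thinned cells, also chosen after the results were seen. The acrocentric outcome was changed to undecided after it was seen. On 18 chromosomes and joined chromosomes the longest inner stretch without values was used as a landmark, which in hg19 holds the centromere. Bins within 5 Mb of it were contacted in 27.0% ± 4.85 (SD, n = 51), against 31.8% ± 3.52 for other bins, and were lower in 49 cells. Chromosomes did not share this direction, with 11 lower and 7 higher. On chromosome 3 the flanks were contacted in 73.0% and other bins in 35.3%, while on chromosome 18 the values were 18.4% and 51.2%. With flanks of 2 Mb the difference was -1.82 points, and with flanks of 10 Mb it was -6.55.

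Chromosomes varied between cells more than independent bins would. Relative to the genome's share, the SD over cells was 9.56 points on chromosome 15, 7.45 on chromosome 21 and 7.03 on chromosome 13. Draws that kept each bin's frequency and each cell's share but let bins vary independently gave means of 1.72, 1.70 and 1.69. Relative to the draws, these SDs were 5.57, 4.37 and 4.15 times as large, below chromosome 12 (7.66 times) and chromosome 2 (6.83 times). On 21 of the 22 chromosomes and joined chromosomes the SD exceeded the highest of 100 such draws. Neighbouring bins varied together, with a correlation above the baseline of 0.437 for adjacent bins, which by itself raises these SDs. The excess therefore does not show that chromosomes vary as units. Single cells stood out, with chromosome 5 contacted in 10.2% of its bins in cell 42, against a mean of 36.9%. Cell 42 also had the lowest contact share of the genome.

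Cells differed in their total contact, with an SD of 3.56 points, and cells with more reads or more background had more contact. Over the 51 cells, which count as 1 sample, contact share correlated with reads (Pearson's r = 0.710, Spearman's rho = 0.706, r = 0.643 without the 2 farthest cells) and with the share of reads in rarely contacted bins (r = 0.661, rho = 0.647, r = 0.686 without the 2 farthest). The latter bins were chosen from the same calls and include 1344 contacted in 1 cell and 763 in 2, so this relation is partly built in. Reads and background also rose together (r = 0.569, rho = 0.463), so the 2 relations are not separate. Thinning all cells to one depth left an SD of 2.75 points, or 0.773 of its former value (95% bootstrap interval over cells 0.737 to 0.810). The interval spans the bound of 0.75 set against depth but lies above the bound set for it. This argues against unequal reads at calling as the whole cause but not against a part. The original reads still correlated with the thinned share (r = 0.660, rho = 0.688, r = 0.594 without the 2 farthest). All thinned cells held the same number of reads, so unequal reads at calling do not explain that relation. Thinning keeps each cell's profile, including its background, so traits that went with the original reads are not excluded. Subtracting each cell's mean OE in rarely contacted bins left 0.927 of the SD (0.903 to 0.955) but changed only 1.74% of contacts, and an earlier form with rescaling changed 0 by construction, so neither decides on background. No biological explanation was tested.

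Contacts varied together over distances of 20 Mb, and a gain or loss of whole chromosomes in single cells may contribute. Dividing each chromosome's OE by its level in bins contacted in at least 90% of cells left 0.618 of the correlation at 20 Mb (95% bootstrap interval over chromosomes 0.539 to 0.691), between the bounds set for and against this cause. The level is an estimate from the chromosome's own OE in the same cell. Dividing by it therefore also removes a change in contact of the whole chromosome, so copy number stays open. Levels were taken on the 16 chromosomes with at least 20 such bins, which leave out chromosomes 15, 16, 17, 19 and 21 and the joined chromosome 22:9. Thinning, which gives all cells the same reads, left 0.759 (0.630 to 0.872). On bins of intermediate frequency after thinning, the correlation at 20 Mb was 0.0537, against at most 0.00973 in 100 draws. This argues against unequal reads as the whole cause but not against a part. Thinning adds sampling noise, which lowers a correlation whatever its cause, so the drop does not measure such a part. Each cell's share had already been subtracted, so the test was weak for a factor of the whole cell. If the arms of a chromosome varied separately, bins on the same arm would correlate more, but the difference was -0.0189 (-0.0668 to 0.0217) over 7 chromosomes, with an exact sign-flip p = 0.5. The rule set beforehand counts this outcome against separate arms. The hypothesis is left undecided here, in departure from that rule, since the interval includes positive differences and 4 of the 7 chromosomes were higher on the same arm. No biological explanation was tested by a group of the design.

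Acrocentric chromosomes, which carry ribosomal DNA and gather at nucleoli, may vary together. Over 4 of them the mean correlation between chromosomes was 0.00214, inside the range of -0.0131 to 0.0118 that held 95% of all 5985 sets of as many chromosomes (exact two-sided p = 0.378). The test showed no excess, and a small one cannot be ruled out.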
